A study of Mus musculus with 9 samples.

How the data were processed

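RNA-seq libraries of mouse spleen CD4+ T cells were compared in 3 groups of 3 samples, namely control mice, CIA mice and CIA mice given luteolin, with each sample's group taken from its label. Per the labels' protocols, total RNA was extracted with TRIzol, stranded mRNA libraries were prepared and read as pairs on a DNBSEQ-T7 sequencer. Reads were trimmed with Trimmomatic 0.36, per the submitters' processing notes, and mapped with a program written as STRA, version 2.5.3a, per the labels' protocols. The processing notes give mm39 as the build, whereas the protocol names CHOK1GS, a hamster cell line genome, as the reference. The deposited table lists mouse gene names at coordinates other than those of GRCm38, with 1325 of 49198 shared names at the same start, and its coordinates are given here as mm39. The deposited values are raw counts of reads per gene, made by the authors with featureCounts from Subread 1.5.1, per the labels' protocols. Those protocols also name RPKM values and edgeR 3.12.1, whose output was not used, and neither the strand setting, the rule for reads on several genes nor the annotation release is stated.

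The counting was checked on the table itself. Of 84618 values from 1 to 10, 73.4% were even, against 52.8% of values from 201 to 1000, so both mates of a pair appear to have been counted. Short genes lying within well-covered exons of another gene (at least 150 bases, over 5000 counts in the enclosing gene) had counts in 33 of 33 cases on the same strand and in 92 of 92 on the opposite strand, with a median density of 0.754 and 0.498 of the enclosing gene. Counts of overlapping and antisense genes therefore cannot be told apart. The overlap was counted for 306 genes, namely those named by rule with Il17a, Il17f and the gene models Gm12534 and Gm10925. Of the 306, 82 share exonic bases with another gene, 15 of them over more than 25% of their length. No pair of libraries within a group was a duplicate, at a chi-square of at least 5.51 per degree of freedom over genes with 20 counts or more.

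The counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Of 56860 genes, 17069 were at 0 in all 9 libraries, and filterByExpr with the groups kept 19348. Libraries were scaled by TMM, with factors between 0.95 and 1.02. A quasi-likelihood model with a term per group was fitted to all 9 libraries, and each pair of groups was compared with glmQLFTest, 2-sided, with Benjamini-Hochberg adjustment over the tested genes within a comparison and a threshold of 0.05. Standard errors are the size of the log2 fold change divided by the square root of F. Levels are TMM-scaled CPM with the SD over 3 libraries. For genes with 1 to 3 counts in a group the ratio of summed counts is given with an exact 95% interval, again with counts halved for the mates of a pair, and a count of 0 is taken to allow 3 fragments. Intervals and limits of this kind cover counting error alone, since reads are not independent molecules.

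Lists of genes for 25 programs and 12 sets of cell markers, 37 in all, were fixed before the data were examined, as were the test, the alternatives and the rule for naming genes. By that rule, in CIA against control and in luteolin against CIA, the 8 largest rises and 8 largest falls are named among genes past the threshold with a mean of at least 2 CPM whose groups do not overlap, and the 5 and 5 in luteolin against control. Unnamed gene models, pseudogenes and receptor gene segments were left out of these, and up to 4 members of each list with the smallest p and 19 genes of helper T cells were added. Il17a and Il17f, which the filter left out, are given from the edgeR fit without a filter and from DESeq2. Genes given as further examples of a list or as cell markers were picked after their values were seen. A few genes that the rule names are not reported here. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the 37 lists within a comparison, and again with the correlation estimated for each list and with fry. Genes changed in opposite directions by CIA and by luteolin were set beside the number for independent lists and beside 20 simulated data sets in which the treated libraries were drawn from the CIA means.

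The procedure was tested on simulated data with the same depth and the fitted spread of each gene, in which 200 of 19348 genes were changed, 50 at each fold. Genes were drawn independently with the same spread in all groups. In the data CIA libraries were more uneven and 45.0% to 51.1% of genes passed, so recovery and false calls there may differ. In CIA against control 40% of changes of 1.5-fold were recovered, 78% of 2-fold, 98% of 4-fold and 100% of 8-fold, and 10 of 19148 unchanged genes were called, 5.95% of the calls. In luteolin against CIA 30%, 80%, 100% and 100% were recovered with 12 unchanged genes called, and in luteolin against control 36%, 88%, 100% and 100% with 12. The alternatives were DESeq2 size factors, no filter or a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the 6 libraries compared, a minimum fold of 2, leaving out immunoglobulin, haemoglobin and mitochondrial genes, a replicate block, and leaving out each library in turn. Counts halved, and genes sharing exonic bases left out, were added after the data were seen. Input was read with the R package data.table (version 1.17.8), overlaps were found with bedtools 2.31.1, and plots were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.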

Results

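RNA from spleen cells described as CD4+ T cells was sequenced in 9 mouse libraries, 3 in each of 3 groups. The groups were mice labelled control, mice labelled CIA, and CIA mice given luteolin, a plant flavone. The series title names RA and the differentiation of Th17 cells, the helper T cells that make IL-17. The libraries labelled control held 40553934, 38520680 and 31234177 counts, those of CIA 35670309, 34384597 and 31851523 and those of CIA with luteolin 41815573, 39074896 and 33436951. Of 56860 genes in the table, 17069 had no counts in any library and 19348 were tested. The labels do not say whether replicates are separate animals, pools or technical replicates, so p-values measure the spread between these samples, and not between animals as such. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 5.51 or more for every pair, and pairs of CIA libraries differed most, at 32.2 to 114. Levels are means ± SD in CPM, counts scaled to library size by TMM, with n = 3, and changes are log2 fold changes ± SE from edgeR.

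Cd4, which encodes the surface protein that names the cell type in the labels (chromosome 6, 124841655 to 124865184, build mm39, minus strand), was at 2.92 ± 0.639 CPM in the libraries labelled control (SD, n = 3). It was at 128 ± 39.6 CPM in CIA and at 104 ± 4.57 CPM in CIA with luteolin, a 43.6-fold rise in CIA over control (log2 fold change 5.44 ± 0.26, adjusted p = 5.50e-07). Cd8a, which marks cytotoxic T cells, went the other way, from 17.6 ± 2.83 CPM in the libraries labelled control to 4.77 ± 0.678 in CIA and 4.15 ± 0.827 with luteolin. The T cell receptor chain gene Cd3e was at 13.5 ± 1.64, 38.6 ± 12.1 and 25.1 ± 1.71 CPM in the same order. The B cell receptor chain gene Cd79a was at 116 ± 6.14 CPM in the libraries labelled control, 52.8 ± 28.6 in CIA and 26.2 ± 3.61 with luteolin. S100a9, an abundant neutrophil transcript, was at 1648 ± 242, 6744 ± 1806 and 3971 ± 275 CPM. In every library S100a9 was above Cd3e. Each direction given against control rests on those libraries.

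**Figure D1:**
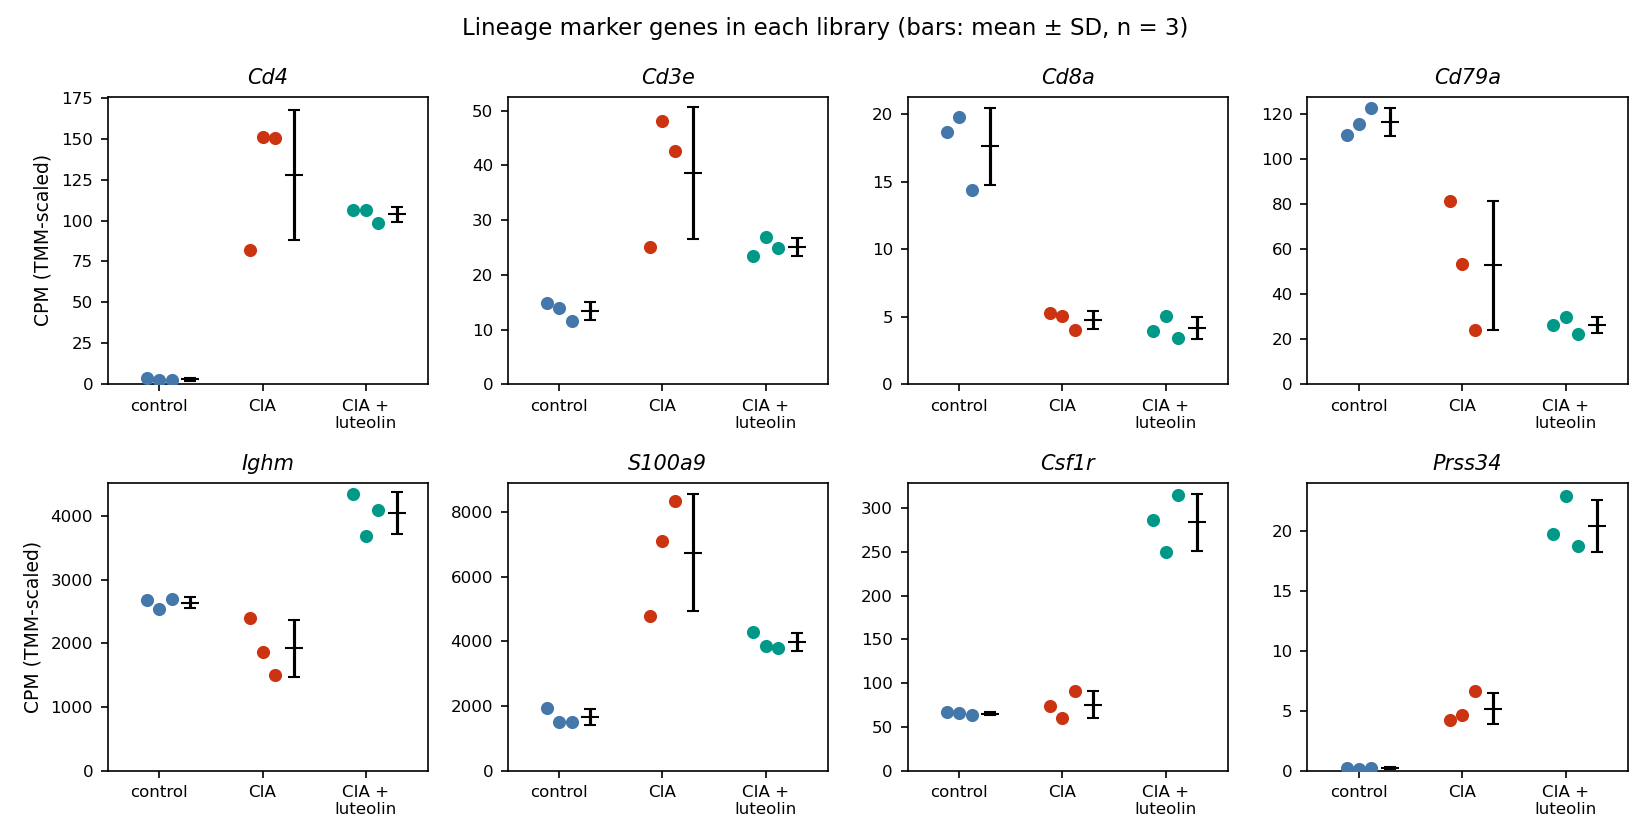
Levels of 8 lineage genes in each library, in TMM-scaled CPM on the vertical axis, with 1 point per library and the mean ± SD of the 3 libraries of a group as a bar. Cd4 lies at 2.92 CPM in the libraries labelled control and above 80 CPM in all others, while Cd8a and Cd79a are highest in the libraries labelled control.

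The comparison of CIA with control addresses what differs in these cells in the disease group. Rora, a nuclear receptor of Th17 cells, rose from 22.4 ± 1.41 to 123 ± 58.5 CPM (log2 fold change 2.46 ± 0.29, adjusted p = 0.000104). Ifit3, an antiviral effector of the type I interferon response, fell from 131 ± 6.92 to 7.87 ± 0.681 CPM (-4.05 ± 0.13). Mki67, a marker of dividing cells, fell from 756 ± 6.62 to 253 ± 33.4 CPM, and the glucose transporter gene Slc2a3 rose from 41.9 ± 0.436 to 199 ± 59.6 CPM. In all, 9886 of the 19348 genes passed an adjusted p of 0.05, 5150 higher and 4736 lower. The spread behind the 9886 genes includes the luteolin libraries, which are more even than those of CIA. In a fit of only the 6 libraries compared 8262 genes passed. For 11363 genes, 58.7% of those tested, the 3 libraries of one group all lay above or below those of the other, where chance gives 10%.

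Of the 22 tested genes of the Th17 list, 18 rose, 1 fell and 3 did not pass the test (20 passed when adjusted over the list alone). The list as a whole was called higher, with a median log2 fold change of 1.91 (camera, adjusted p = 1.03e-06, adjusted p = 0.177 with an estimated correlation). Il23r, the receptor subunit for IL-23, rose by 2.27 ± 0.43 to 2.90 ± 1.77 CPM (adjusted p = 0.00162). Il22, a cytokine of Th17 cells, rose from 0.0548 ± 0.00734 to 0.601 ± 0.466 CPM (3.36 ± 0.67; 2.58 without CIA replicate 3, where Il23r was at 1.68). Il22 had only 2 counts in each library labelled control and 16, 8 and 34 in CIA, so its fold rests on few reads. Stat3, the transcription factor downstream of IL-6 and IL-23, rose by 0.36 ± 0.08. Ccr6, the chemokine receptor of Th17 cells, which is also high on B cells, was at 42.9 ± 5.30 CPM in the libraries labelled control and 24.1 ± 17.4 in CIA (-0.83 ± 0.39, adjusted p = 0.101; -1.56 and past the threshold without CIA replicate 1). For Ccr6 49.4% of exonic bases overlap another gene. The IL-17 genes were left out of the main test by the filter on low counts, and are given from the edgeR fit without that filter. Il17f had 0, 1 and 6 counts in the libraries labelled control and 4, 2 and 4 in CIA, and did not pass (0.57 ± 0.87, adjusted p = 0.697). Il17a had no counts in any library labelled control or CIA. A count of 0 in a library is compatible with up to 3 expected fragments, or 6 counts if both mates of a pair were counted, so low levels of Il17a were not detectable at this depth. Counts assigned to Il21, a cytokine of Th17 and follicular helper cells, rose from 0.405 ± 0.0996 to 32.1 ± 8.02 CPM (6.32 ± 0.26), but the antisense gene Gm12534, which covers 8.92% of its exonic bases, held a count equal to 96.4% of that of Il21. At the preset correlation, the 9 other ways of splitting these 6 libraries into 3 and 3 also called 5 to 20 lists each, while calling no gene. Those splits mix both groups on each side and keep part of their difference, so they do not measure false calls.

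Lists of other helper programs were tested in the same way. In the regulatory T cell list 18 of 22 genes rose and 1 fell (19 adjusted over the list alone, camera adjusted p = 3.17e-09, adjusted p = 0.177 with an estimated correlation). Foxp3, the lineage factor of regulatory T cells, rose from 17.4 ± 1.35 to 31.4 ± 5.39 CPM (0.85 ± 0.12), with 31.5% of its exonic bases shared with other genes, and the inhibitory receptor Tigit rose by 4.21 ± 0.25. Gm36995, which overlaps 373 of the 4577 exonic bases of Foxp3 on the opposite strand, held 12228 counts over all libraries against 13351 for Foxp3. The follicular helper list was called higher both ways, with 9 of 14 genes up and 4 down (13 adjusted over the list alone, camera adjusted p = 8.04e-08, adjusted p = 0.0278 with an estimated correlation). Its factor Bcl6 rose from 24.6 ± 0.241 to 84.1 ± 15.8 CPM (1.77 ± 0.12), Icos, a costimulatory receptor, by 4.96 ± 0.43, and Cd40lg, the helper cell ligand of CD40, by 5.54 ± 0.40 (6.27 without control replicate 1). In the Th1 list 11 of 18 genes rose and 3 fell (15 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.333 with an estimated correlation). Ifng was at 0.0756 ± 0.0750 and 0.367 ± 0.150 CPM (2.15 ± 0.65, adjusted p = 0.0184; 3.03 and past the threshold without control replicate 1, 2.12 without control replicate 2 and 1.84 without CIA replicate 1, the latter 2 not past the threshold), with 25.9% of its exonic bases shared. Tbx21 had a log2 fold change of 0.58 ± 0.18 (adjusted p = 0.0208; 0.44 without control replicate 3 and 0.51 without CIA replicate 2, neither past the threshold). In the Th2 list 7 of 10 genes rose and 1 fell (10 adjusted over the list alone, camera adjusted p = 0.00107, adjusted p = 0.177 with an estimated correlation). Gata3 went up from 1.27 ± 0.361 to 9.88 ± 5.99 CPM. Il4 did not pass (1.55 ± 0.64, adjusted p = 0.0638), but it did without CIA replicate 1, at 1.99. The anti-inflammatory cytokine gene Il10 rose by 1.72 ± 0.25 and Il2ra, the high-affinity IL-2 receptor chain, by 0.96 ± 0.15. Among 24 genes of T cell receptor signalling 17 rose and 3 fell (20 adjusted over the list alone, camera adjusted p = 2.81e-06, adjusted p = 0.177 with an estimated correlation). Zap70 was up by 2.84 ± 0.27 and Cd28 by 2.89 ± 0.31. Of 20 genes of IL-6 and STAT3 signalling 12 rose and none fell (12 adjusted over the list alone, camera adjusted p = 0.000170, adjusted p = 0.273 with an estimated correlation). Of 28 genes of effector and memory activation 15 rose and 7 fell (23 adjusted over the list alone, camera adjusted p = 0.00147, adjusted p = 0.177 with an estimated correlation). These values stand beside the 43.6-fold difference in Cd4 itself, and the Th2 list also beside a rise of all 9 mast cell and basophil genes.

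**Figure D2:**
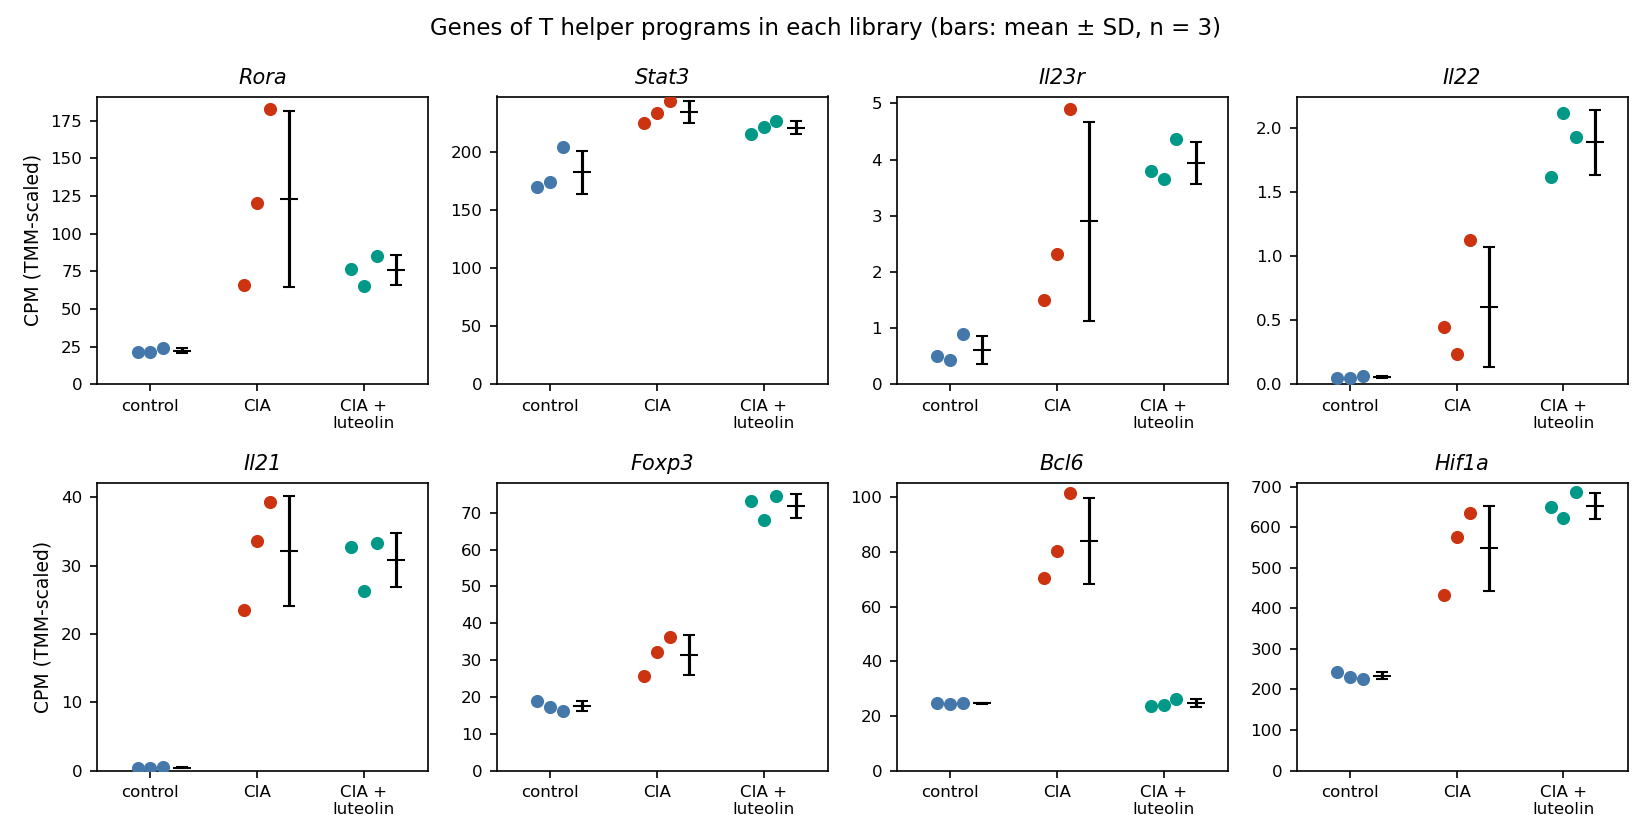
Levels of 8 genes, 7 of helper T cell programs and the hypoxia factor Hif1a, in each library, in TMM-scaled CPM, with points for libraries and bars for the mean ± SD of 3 libraries. Rora is lowest in the libraries labelled control, Bcl6 is high in CIA alone, and Foxp3 is highest with luteolin, at 71.9 CPM.

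In the interferon response list 42 of 47 genes fell, 3 rose and 2 did not pass (46 adjusted over the list alone), with a median of -1.56 (camera adjusted p = 6.63e-55, adjusted p = 0.0278 with an estimated correlation). Irf7, the master regulator of interferon production, fell from 105 ± 4.47 to 11.3 ± 2.42 CPM, and Ifi44 fell by 4.38 on the log2 scale (SE 0.28; -5.01 without CIA replicate 1). In the same libraries 10 of 19 genes of the macrophage list fell and 5 rose, with a median of -0.84 (15 adjusted over the list alone, camera adjusted p = 0.000480, adjusted p = 0.177 with an estimated correlation). Among cell division genes 44 of 56 genes of G2 and M phase fell and 2 rose (48 adjusted over the list alone, camera adjusted p = 2.50e-17, adjusted p = 0.131 with an estimated correlation). In S phase 30 of 44 fell and 2 rose (34 adjusted over the list alone, camera adjusted p = 2.87e-07, adjusted p = 0.177 with an estimated correlation). The spindle gene Tpx2 changed by -1.48 ± 0.11 and the kinetochore motor gene Cenpe by -1.95 ± 0.13. Glycolysis genes rose, 20 of 22 with none lower (20 adjusted over the list alone, camera adjusted p = 5.27e-12, adjusted p = 0.177 with an estimated correlation). Pkm, pyruvate kinase, rose by 2.43 ± 0.24 and Slc16a3, a lactate exporter, by 2.62 ± 0.23. Of the hypoxia list 18 of 25 genes rose and none fell (18 adjusted over the list alone, camera adjusted p = 1.09e-08, adjusted p = 0.273 with an estimated correlation). The oxygen sensor gene Egln3 rose by 3.36 ± 0.27, and Hif1a rose from 233 ± 8.63 to 548 ± 105 CPM. In the same libraries the neutrophil transcript S100a9 rose from 1648 ± 242 to 6744 ± 1806 CPM. Of 65 genes of oxidative phosphorylation 38 fell and 1 rose (43 adjusted over the list alone), with a median of only -0.34 (camera adjusted p = 0.000157, adjusted p = 0.239 with an estimated correlation).

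Lists of markers of other cells were tested too. Neutrophil and granulocyte precursor genes rose, 16 of 19 with none lower (16 adjusted over the list alone, camera adjusted p = 3.62e-15, adjusted p = 0.110 with an estimated correlation). Mmp9, a neutrophil gelatinase, rose from 26.4 ± 2.32 to 173 ± 45.1 CPM. All 9 mast cell and basophil genes rose (9 adjusted over the list alone, median 3.22, camera adjusted p = 4.13e-12, adjusted p = 0.110 with an estimated correlation). B cell genes fell, 13 of 18 with none higher (13 adjusted over the list alone, median -1.23, camera adjusted p = 0.000665, adjusted p = 0.509 with an estimated correlation). Members of the monocyte and macrophage list that fell included the adhesion gene Vcam1 at -3.66 ± 0.20 and the factor Spic at -2.25 ± 0.15. Lyz2, a general myeloid lysozyme gene, rose by 2.40 ± 0.26 and the receptor gene Csf1r did not pass (0.20 ± 0.14).

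The largest rises by the rule fixed for naming genes were in Spp1, the secreted phosphoprotein osteopontin (chromosome 5, 104582984 to 104588916), Col5a1, Fxyd2, Sh3gl3, Col24a1, Il21, Sostdc1 and Serpina3b. Spp1 went from 13.3 ± 4.84 to 1777 ± 1593 CPM (7.07 ± 0.70), and without CIA replicate 3 its change was 6.04. The collagen gene Col5a1 rose by 7.05 ± 0.53 and Sh3gl3 by 6.86 ± 0.53. Serpina3b had 240 counts in CIA against 3 in the libraries labelled control, a ratio of 88.2 with an exact 95% interval of 29.8 to 430.5 with each count taken as independent. With counts halved, since both mates of a pair appear to have been counted, it was 20.2 to 1238, for counting error alone, and the fitted change was 5.71 without control replicate 1 and 9.49 without control replicate 3. The largest falls were in H2-M2, Pmp22, Cd5l, Marco, Siglec1, Hebp1, Col15a1 and Ifi44. Marco, a scavenger receptor of macrophages, fell from 31.8 ± 13.2 to 0.592 ± 0.260 CPM, and Cd5l, a secreted macrophage protein, from 30.1 ± 13.0 to 0.444 ± 0.532 (-6.01 ± 0.59; -7.73 without CIA replicate 1). Levels in CIA were close to 0 for Pmp22 (0.111, 0 and 0 CPM in replicates 1 to 3) and for the macrophage lectin Siglec1 (0, 0 and 0.132 CPM), so their fitted folds depend on a single library. Leaving out a library also moved Fxyd2 from 6.99 to 5.81 (CIA replicate 3), Col24a1 from 6.71 to 7.53 (control replicate 3) and H2-M2 from -7.17 to -8.07 (CIA replicate 1). At a fold of at least 2 as well, 4148 genes passed, 64.6% of them higher.

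The comparison of CIA with luteolin against CIA addresses what the treatment changed, with Th17 differentiation named in the series title. The Th17 list was not called in either direction (median log2 fold change -0.18, camera adjusted p = 0.467). Foxp3 rose from 31.4 ± 5.39 to 71.9 ± 3.30 CPM (1.20 ± 0.12, adjusted p = 2.95e-05), and Il23a, the IL-23 subunit made by myeloid cells, fell from 22.7 ± 11.3 to 2.00 ± 0.340 CPM (-3.50 ± 0.38, adjusted p = 4.39e-05). Foxp3 shares 31.5% of its exonic bases with other genes, among them Gm36995, so part of its counts may be theirs. Ifit3 rose from 7.87 ± 0.681 to 176 ± 26.6 CPM, and Mki67 rose from 253 ± 33.4 to 1446 ± 14.9 CPM. Of 19348 genes 9148 passed, 4462 higher and 4686 lower, and 10782 genes, 55.7%, had groups that did not overlap, against 10% by chance. The spread behind the 9148 genes includes the libraries labelled control, which are more even than those of CIA. In a fit of only the 6 libraries compared 8043 genes passed.

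In the Th17 list 4 of 22 genes rose, 5 fell and 13 did not pass (9 adjusted over the list alone, camera adjusted p = 0.467). Rora was at 75.8 ± 9.81 CPM against 123 ± 58.5 in CIA and did not pass (-0.70 ± 0.28, adjusted p = 0.0576), although it was called lower without CIA replicate 1 (-0.99) and by DESeq2 (-0.68). Il23r did not pass either (0.45 ± 0.37, adjusted p = 0.344), but it was called higher without CIA replicate 3 (1.04). Ccr6 had a change of -0.79 ± 0.40 (adjusted p = 0.126; -1.18 and called without CIA replicate 3). Il22 rose from 0.601 ± 0.466 to 1.89 ± 0.253 CPM (1.67 ± 0.44, adjusted p = 0.00943; 2.45 without CIA replicate 3). Neither Il21 nor Stat3 passed (adjusted p = 0.809 and 0.438). Il17f, a gene of IL-17 left out by the filter, had 26, 9 and 24 counts with luteolin against 4, 2 and 4 in CIA, or 0.622, 0.230 and 0.718 CPM against 0.112, 0.0582 and 0.126. Each treated library was above each CIA library. In the edgeR fit without a filter Il17f was higher with luteolin (2.35 ± 0.71, adjusted p = 0.00537), and DESeq2 called it as well (2.39, adjusted p = 0.0332). Il17a had 2, 2 and 0 counts with luteolin and none in CIA, and did not pass in the fit without a filter (adjusted p = 0.407). The 4 genes with the smallest p were Nfkbiz, an atypical inhibitor of the NF-kB family, at -2.31 ± 0.27, the TGF-beta mediator Smad3 at -0.89 ± 0.12, Tmem176a at 1.03 ± 0.23 and the aryl hydrocarbon receptor Ahr at -0.45 ± 0.10.

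The regulatory list had 11 of 22 genes up and 4 down (15 adjusted over the list alone) and was not called (camera adjusted p = 0.134), but it was called higher without CIA replicate 3 (0.0343) and without a filter on low counts (0.00534), with 0.00534 to 0.776 over the alternatives tested with camera. Fry, which does not compare a list with other genes, gave 0.0308. Besides Foxp3, the integrin gene Itgae rose by 2.35 ± 0.16, Tnfrsf9 by 1.28 ± 0.15 and Il2ra by 0.73 ± 0.14, while Il10 fell from 23.7 ± 9.71 to 10.1 ± 0.620 CPM. The follicular list had 6 of 14 genes down and 1 up (7 adjusted over the list alone, camera adjusted p = 0.134). It was called lower without CIA replicate 1 (0.0397), without CIA replicate 3 (0.0404) and without a filter on low counts, with 0.0397 to 0.326 over the alternatives tested with camera, and fry gave 0.00114. Bcl6 fell from 84.1 ± 15.8 to 24.7 ± 1.41 CPM (-1.77 ± 0.12, adjusted p = 1.99e-06), and Icos fell by 1.58 on the log2 scale. Of the Th1 genes, with 7 up and 6 down among 18 (13 adjusted over the list alone, camera adjusted p = 0.819, with a median of -0.08 although camera ranked the list upward), Tbx21 had a change of -1.21 ± 0.19 (adjusted p = 0.000434). Ifng had 1.39 ± 0.49 (adjusted p = 0.0368), a call lost without CIA replicate 2 (1.11) or without luteolin replicate 1, 2 or 3 (1.33, 1.44 and 1.48). The Th2 list had 3 of 10 genes up and 1 down (4 adjusted over the list alone, camera adjusted p = 0.691) and was not called. Neither Gata3 (-0.79 ± 0.37, adjusted p = 0.102; -1.14 and called without CIA replicate 1) nor Il4 (0.66 ± 0.52, adjusted p = 0.324) passed. T cell receptor signalling genes fell, 13 of 24 against 2 higher (16 adjusted over the list alone, camera adjusted p = 0.00371, adjusted p = 0.474 with an estimated correlation). The lists of IL-6 and STAT3 signalling (4 higher and 8 lower of 20, 12 adjusted over the list alone, camera adjusted p = 0.279) and of chemokine receptors and migration (8 higher and 7 lower of 24, 15 adjusted over the list alone, camera adjusted p = 0.249) were not called. For the chemokine receptor list the adjusted p was 0.0295 to 0.578 over the alternatives tested with camera, so not all left it uncalled, and fry gave 0.000964. In the same libraries Cd4 was not called (-0.30 ± 0.21, adjusted p = 0.253; -0.53 and called without CIA replicate 1), and Cd3e fell by 0.62 on the log2 scale (adjusted p = 0.0267).

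All but 1 of the 47 interferon response genes rose (46 adjusted over the list alone, median 2.36, camera adjusted p = 1.02e-87, adjusted p = 0.0197 with an estimated correlation). Irf7 went from 11.3 ± 2.42 to 213 ± 17.6 CPM and the antiviral gene Oasl2 rose by 3.92 ± 0.10. Beside them, the monocyte and macrophage list rose, 15 of 19 genes with none lower (16 adjusted over the list alone, median 3.20, camera adjusted p = 2.96e-19, adjusted p = 0.0204 with an estimated correlation). Csf1r, the receptor for the growth factor of macrophages, rose from 75.2 ± 15.3 to 284 ± 32.4 CPM, and Vcam1 rose by 5.49 ± 0.20. G2 and M phase genes rose, 46 of 56 against 2 lower (49 adjusted over the list alone, camera adjusted p = 2.79e-35, adjusted p = 0.0580 with an estimated correlation). So did 33 of 44 S phase genes, with 2 lower (36 adjusted over the list alone, camera adjusted p = 6.69e-11, adjusted p = 0.118 with an estimated correlation). In these same libraries Mpo, myeloperoxidase, rose from 1.54 ± 0.339 to 261 ± 28.3 CPM. Of the oxidative phosphorylation genes 60 of 65 rose and none fell (61 adjusted over the list alone, median 0.59, camera adjusted p = 4.42e-11, adjusted p = 0.114 with an estimated correlation). Glycolysis genes fell, 12 of 22 with 2 higher (14 adjusted over the list alone, camera adjusted p = 0.0101, adjusted p = 0.713 with an estimated correlation). Slc2a3 went from 199 ± 59.6 to 56.7 ± 2.40 CPM. Of the hypoxia list 15 of 25 fell and 2 rose (17 adjusted over the list alone, camera adjusted p = 0.00421, adjusted p = 0.713 with an estimated correlation). In the same libraries the neutrophil transcript S100a9 fell from 6744 ± 1806 to 3971 ± 275 CPM, and Ly6g changed by -2.45 ± 0.26. Hif1a itself was at 653 ± 32.2 CPM and did not pass (0.25 ± 0.12, adjusted p = 0.108; 0.37 and called without CIA replicate 3).

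**Figure D3:**
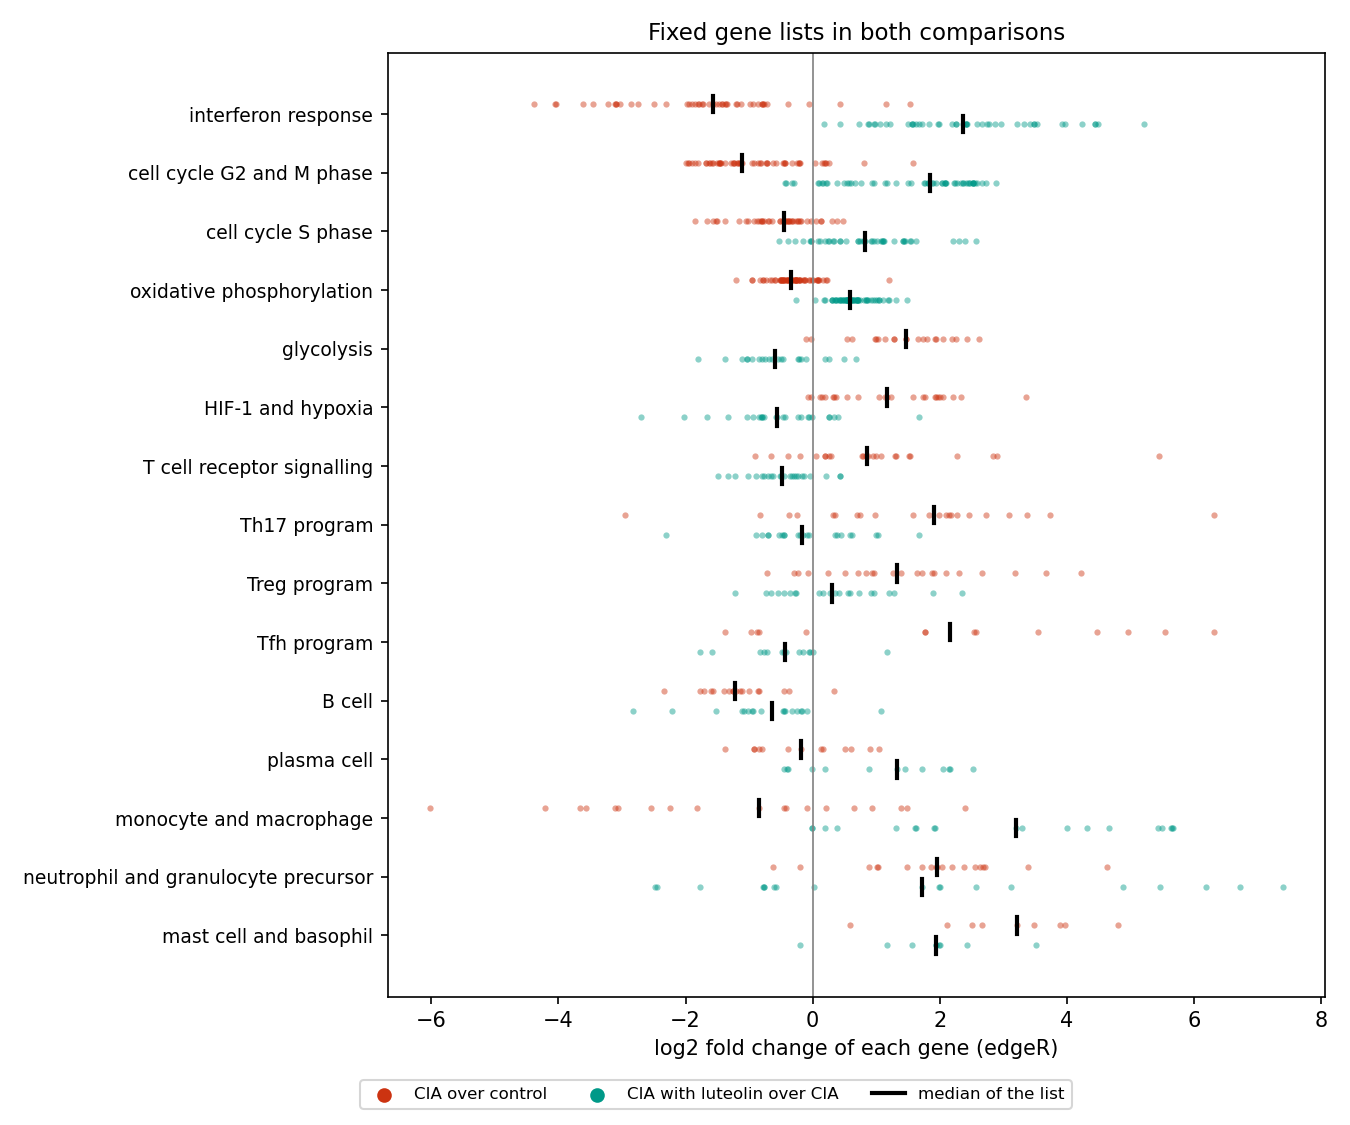
Log2 fold change of each tested gene of 15 fixed lists, with 1 point per gene, red for CIA over control, green for CIA with luteolin over CIA, and a black bar at the median of each list. The medians of the interferon list lie at -1.56 and 2.36, and those of the Th17 list at 1.91 and -0.18.

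By the naming rule the largest rises were in Siglec1, Mpo, Pmp22, H2-M2, Elane, Ifi205, Mrc1 and Mertk. Elane, neutrophil elastase, went from 0.260 ± 0.124 to 27.8 ± 2.91 CPM and Siglec1 from 0.0441 ± 0.0764 to 16.6 ± 1.56. The mannose receptor Mrc1 rose by 6.40 ± 0.35 and the efferocytosis receptor Mertk by 6.40 ± 0.34 (7.31 without CIA replicate 3). Siglec1 had counts only in replicate 3 of CIA and Pmp22 only in replicate 1, and H2-M2 went from 7.13 to 8.03 without CIA replicate 1. The largest falls were in Calr4, Spp1, Nek10, Myl2, Csf3, Il23a, F3 and S100a7a. Csf3, the granulocyte colony-stimulating factor, fell from 55.2 ± 35.9 to 4.69 ± 1.71 CPM, and Spp1 from 1777 ± 1593 to 61.9 ± 23.8. Without CIA replicate 3 the changes were -3.81 for Spp1, -2.90 for Csf3, -3.20 for Nek10 and -2.80 for F3, all still called. Among neutrophil and precursor genes 10 of 19 rose and 8 fell (18 adjusted over the list alone, camera adjusted p = 4.66e-07, adjusted p = 0.243 with an estimated correlation). The ficolin gene Fcnb rose by 6.18 ± 0.24 and Ctsg, cathepsin G, by 4.89 ± 0.21, whereas the surface marker Ly6g changed by -2.45 ± 0.26 and Retnlg by -2.48 ± 0.22. Of the mast cell and basophil list 8 of 9 genes rose with none lower (8 adjusted over the list alone, camera adjusted p = 4.66e-07, adjusted p = 0.151 with an estimated correlation). B cell genes were 4 lower and 1 higher of 18 (5 adjusted over the list alone), and the list was not called (adjusted p = 0.331), but it was called lower without CIA replicate 3 (adjusted p = 3.26e-07; 3.26e-07 to 0.883 over the alternatives tested with camera). At a fold of at least 2 as well, 3658 genes passed, 55.7% of them higher.

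**Figure D4:**
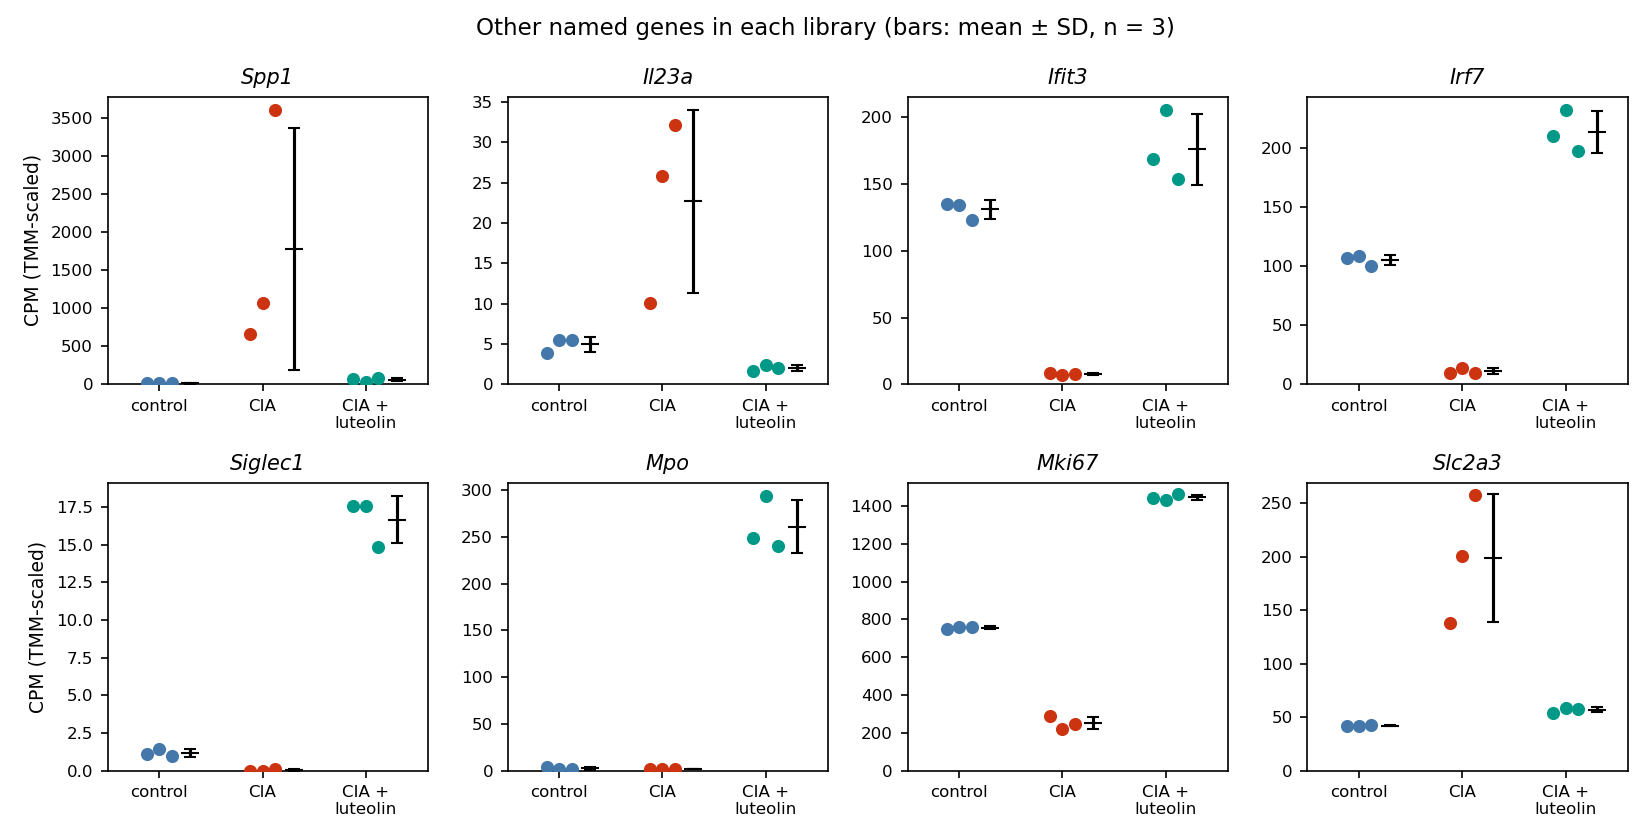
Levels of 8 named genes in each library, in TMM-scaled CPM, with 1 point per library and bars for the mean ± SD of 3 libraries. Ifit3, Irf7 and Mki67 are lowest in CIA, Spp1, Il23a and Slc2a3 are highest there, and Mpo is above 200 CPM with luteolin alone.

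The comparison of CIA with luteolin against control shows how far treated mice were from the libraries labelled control. Elane, neutrophil elastase, was at 27.8 ± 2.91 CPM against 0.0504 ± 0.050 (8.92 ± 0.36; 9.78 without control replicate 1), and Prss34, a basophil protease, at 20.4 ± 2.18 against 0.181 ± 0.0743 (log2 fold change 6.79 ± 0.28, adjusted p = 2.20e-07). Rora was higher (1.76 ± 0.29, adjusted p = 0.000667), as were Il22 (5.03 ± 0.60), Il23r (2.71 ± 0.43) and Foxp3 (2.04 ± 0.13). So was Il17f in the fit without a filter (2.92 ± 0.75, adjusted p = 0.000680). These changes stand beside a Cd4 difference of 5.14 ± 0.26. Il22 had only 2 counts in each library labelled control, so its fold rests on few reads. Bcl6 did not pass, at 24.7 ± 1.41 against 24.6 ± 0.241 CPM (0.01 ± 0.12, adjusted p = 0.975), and Cd79a, a chain of the B cell receptor, was at 26.2 ± 3.61 against 116 ± 6.14 CPM. In all 8708 genes passed, 4683 higher and 4025 lower, and 12246 genes, 63.3%, had groups that did not overlap, against 10% by chance. The spread behind that count includes the more uneven CIA libraries, and in a fit of only the 6 libraries compared 10792 genes passed.

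Of the Th17 list 15 of 22 genes were higher and 5 lower (20 adjusted over the list alone, median 1.89, camera adjusted p = 0.000170, adjusted p = 0.307 with an estimated correlation). Ccr6 was among those lower (-1.62 ± 0.40), and Stat3 was higher by 0.28 ± 0.08 (adjusted p = 0.0193; 0.23 and 0.24 without control replicates 1 and 2 and 0.26 without luteolin replicate 3, none past the threshold). The regulatory list had 17 of 22 genes higher and none lower (17 adjusted over the list alone, camera adjusted p = 7.22e-15, adjusted p = 0.104 with an estimated correlation). The follicular list had 8 higher and 4 lower of 14 (12 adjusted over the list alone, camera adjusted p = 0.000232, adjusted p = 0.0462 with an estimated correlation). Interferon response genes were 31 higher and 6 lower of 47 (41 adjusted over the list alone, camera adjusted p = 9.33e-10, adjusted p = 0.247 with an estimated correlation). The macrophage list beside them had 16 genes higher and 1 lower of 19 (17 adjusted over the list alone, camera adjusted p = 1.52e-10, adjusted p = 0.0222 with an estimated correlation). All 19 neutrophil and precursor genes were higher (19 adjusted over the list alone, median 3.47, camera adjusted p = 3.71e-40, adjusted p = 0.0222 with an estimated correlation). So were all 9 mast cell and basophil genes (9 adjusted over the list alone, median 5.42, camera adjusted p = 4.24e-29, adjusted p = 0.0230 with an estimated correlation). B cell genes were 17 lower and 1 higher of 18 (18 adjusted over the list alone, median -2.10, camera adjusted p = 4.69e-06, adjusted p = 0.446 with an estimated correlation). The largest rises were in Elane, Serpina3b, Muc13, Samd5 and Prss34, and the largest falls in Fcamr, Shisa8, Crisp3, Fcer2a and Shank1. The mucin gene Muc13 was at 43.4 ± 2.50 against 0.331 ± 0.0404 CPM. Serpina3b had 500 counts against 3, a ratio of 159.6 with an exact 95% interval of 54.3 to 776 (36.9 to 2229 with counts halved), and the fitted change was 6.54 without control replicate 1 and 10.31 without control replicate 3. Fcer2a, the low-affinity IgE receptor of B cells, was at 5.92 ± 0.530 against 35.9 ± 2.96 CPM. Samd5 had counts in control replicate 2 alone among the libraries labelled control, at 0.154 CPM, so its fitted fold depends on that library. At a fold of at least 2 as well, 3669 genes passed, 69.4% of them higher.

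Genes that moved in CIA and in the opposite direction with luteolin were counted across the first and second comparison. Of 9886 genes changed in CIA over control, 5057, or 51.2%, passed in the opposite direction with luteolin, 2677 of them up and then down, such as Bcl6, Slc2a3 and Spp1, and 2380 down and then up, such as Ifit3, Irf7 and Mki67. Another 703 passed in the same direction again, such as Foxp3 and Il22. Independent lists of these sizes would share 2340 genes in opposite directions and 2335 in the same direction. By list, 42 of 47 interferon genes, 43 of 56 G2 and M phase genes and 35 of 65 oxidative phosphorylation genes went down and then up, and 12 of 22 glycolysis genes and 14 of 25 hypoxia genes up and then down. In the Th17 list 4 of 22 genes went up and then down and 4 up and then up again. Of the 5057 genes, 3327, or 65.8%, did not pass the test of luteolin against control, which does not show that they returned to its level. That test takes its spread from all 9 libraries, including the more uneven CIA libraries. Without them 10792 genes passed in place of 8708, so this share may be lower in that fit, where it was not counted. Both comparisons use the same CIA libraries, which alone pushes the fold changes in opposite directions. Across the 19348 genes, which are not independent replicates, Pearson's r between the fold changes was -0.51 (Spearman's rho -0.497). It compares with a mean of -0.135 in 20 simulations in which the treated libraries were drawn from the CIA means (range -0.157 to -0.107), where no gene passed in opposite directions. The covariance was -0.612 against -0.0525 simulated, a difference of -0.559. Luteolin had no effect in those simulations, so they cannot tell a reversal from 3 groups that differ in unrelated ways. Such groups would also show opposite changes and a negative r through the shared CIA libraries. Their r was not simulated, so neither the r of -0.51 nor the 5057 genes show a reversal by luteolin. Between CIA against control and luteolin against control, which share the control libraries, Pearson's r was 0.56. The 3 CIA libraries cannot be split into parts of at least 2, so part or all of the excess over independent lists may come from sharing them.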

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

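The alternatives with overlapping genes left out and with halved counts were chosen after the data were seen, and the others before. Every named gene past the threshold kept its direction under every alternative that gave a value. For genes past it in neither case the sign changed in 4 values in luteolin against CIA and 2 in luteolin against control, all on leaving out 1 library, for Il21 and Bcl6 among others. Of all results on them, 2088 of 2099 results kept their side of the threshold in CIA against control, 2030 of 2076 in luteolin against CIA and 2039 of 2051 in luteolin against control. With a fold of at least 2 the 3 comparisons held 4148, 3658 and 3669 genes, and with overlapping genes left out 5760, 5450 and 5089, with 3005 genes moving in opposite directions, both because fewer genes could pass. With an estimated correlation 2, 2 and 5 lists were called in place of 26, 16 and 24, and the Th17 list in CIA against control had an adjusted p of 0.177. Fry, which does not compare a list with other genes, called 30, 22 and 35. Leaving out 1 library gave 8073 to 11065, 7289 to 9884 and 6835 to 7552 genes, 4031 to 6208 genes in opposite directions, 25 to 26, 16 to 21 and 22 to 24 lists, and for the Th17 list an adjusted p of 2.75e-07 to 3.13e-06 in CIA against control and 0.215 to 0.858 in luteolin against CIA. DESeq2 gave 9950, 9175 and 8662 genes, limma-voom 9895, 9144 and 8779, DESeq2 size factors 9867, 9102 and 8670, no filter 9850, 9443 and 8630, the 6 libraries compared 8262, 8043 and 10792, and halved counts 9532, 8934 and 8535. DESeq2 size factors moved the median of all genes by at most 0.02 (log2). The labels number the replicates 1 to 3 in each group without saying that numbers pair samples, and the data leave a weak pairing possible. Deviations of same-numbered libraries correlated at 0.00654 to 0.144, over 0.1 in 2 of 9 pairs, and those of other pairs at -0.177 to 0.092. Of 9 libraries, 7 correlated best with their own number, and total counts fell from replicate 1 to 3 in every group. A replicate block gave 9794, 9148 and 8764 genes, 5079 in opposite directions, 25, 16 and 23 lists, and 1.10e-06 and 0.472 for the Th17 list. The IL-17 genes, with 4 counts of Il17a and 76 of Il17f over all 9 libraries, were left out by the filter, and their values without it were looked up after the data were seen. No library was left out in turn for them.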

Other observations

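The tests of T cell, CD4 cell, B cell and macrophage shares and of scaling were chosen after the values concerned had been seen, and those of CIA replicate 3 and of other splits before. Genes of platelets and their precursors were higher in CIA than in control, 10 of 13 with none lower (10 adjusted over the list alone, camera adjusted p = 0.000210, adjusted p = 0.278 with an estimated correlation). Pf4, a platelet chemokine, rose from 1.35 ± 0.417 to 4.06 ± 2.00 CPM in edgeR's test, and Itga2b, a platelet integrin, by 2.31 ± 0.26. With luteolin 4 of these genes rose and 1 fell against CIA (5 adjusted over the list alone, camera adjusted p = 0.439). The list was called without CIA replicate 3 at an adjusted p of 0.0404 (0.0404 to 0.883 over the alternatives tested with camera). Genes of the erythroid list were higher in CIA for 4 of 13 members with none lower (4 adjusted over the list alone, camera adjusted p = 0.00137, adjusted p = 0.177 with an estimated correlation). With luteolin 7 of the 13 fell and 2 rose (9 adjusted over the list alone, camera adjusted p = 0.0114, adjusted p = 0.326 with an estimated correlation). That adjusted p was 0.0546 without CIA replicate 3, and 0.00292 to 0.326 over the alternatives tested with camera, while fry, which does not compare a list with other genes, gave 0.000856. The haemoglobin gene Hbb-bs was at 2.21 ± 0.394, 2.13 ± 0.198 and 0.403 ± 0.166 CPM in control, CIA and luteolin. Dendritic cell genes fell in CIA for 7 of 13 members and rose for 1 (11 adjusted over the list alone, camera adjusted p = 0.00163, adjusted p = 0.110 with an estimated correlation). With luteolin 6 rose and 3 fell (9 adjusted over the list alone, camera adjusted p = 0.00570, adjusted p = 0.114 with an estimated correlation). Siglech and Bst2, genes of plasmacytoid dendritic cells, changed by -3.80 ± 0.50 and -1.43 ± 0.13 in CIA and by 3.44 ± 0.51 and 2.77 ± 0.13 with luteolin, and Bst2 is also a member of the interferon list. Plasma cell genes rose with luteolin for 8 of 13 members and fell for 2 (10 adjusted over the list alone, camera adjusted p = 3.24e-06, adjusted p = 0.112 with an estimated correlation). Jchain, which links secreted antibodies, rose by 1.32 ± 0.15.

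Genes of cholesterol synthesis fell in CIA for 15 of 24 members and rose for 1 (16 adjusted over the list alone, camera adjusted p = 0.000793, adjusted p = 0.177 with an estimated correlation). With luteolin 13 of the 24 rose and 1 fell (14 adjusted over the list alone, camera adjusted p = 0.00814, adjusted p = 0.326 with an estimated correlation). Hmgcs1, which makes a precursor of mevalonate, changed by -0.75 ± 0.08 and 0.56 ± 0.08. The unfolded protein response was not called in CIA (camera adjusted p = 0.495). It rose with luteolin for 13 of 26 genes, with 4 lower (18 adjusted over the list alone, camera adjusted p = 0.000780, adjusted p = 0.326 with an estimated correlation), beside the rise of plasma cell genes. Immediate early genes fell with luteolin for 13 of 22 members and rose for 2 (15 adjusted over the list alone, camera adjusted p = 0.00371, adjusted p = 0.349 with an estimated correlation). Jund, a subunit of AP-1 with 52.6% of its exonic bases shared with the antisense gene Gm11175, changed by -1.51 ± 0.11 and the growth arrest gene Btg2 by -1.20 ± 0.09. Antioxidant genes driven by Nrf2 rose in CIA for 18 of 25 members and fell for 2 (22 adjusted over the list alone, camera adjusted p = 0.000601, adjusted p = 0.509 with an estimated correlation). With luteolin 9 of the 25 fell and 5 rose (16 adjusted over the list alone, camera adjusted p = 0.423). The list was called without CIA replicate 1 at an adjusted p of 0.0245, with 0.0245 to 0.892 over the alternatives tested with camera. Nqo1, a quinone reductase, changed by 1.52 ± 0.22 and -1.84 ± 0.23.

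Cd4 was at 2.92 ± 0.639 CPM (mean ± SD, n = 3) in the libraries labelled control against 128 ± 39.6 in CIA, although all libraries are labelled CD4+ T cells. The tables argue against fewer T cells of every kind in the control preparations as the sole cause of this Cd4 difference. In edgeR's fit 11 general T cell genes had a median log2 fold change of 1.304 (0.05 to 2.89), the highest 3.51 with 2 SE added. Cd4 had 5.44, or 4.93 with 2 SE taken away. Fold changes of the 11 genes were all positive, so a smaller share of T cells in the control preparations stays open. Whether T cells of the control preparations lacked CD4 cells stays open: Cd8a and Cd8b1 differed from the median of the general T cell genes by -3.105, and the helper genes Cd40lg and Icos rose by 5.54 (6.27 without control replicate 1) and 4.96, but Foxp3, a gene of regulatory CD4 cells with 31.5% of its exonic bases shared, rose by 0.85, less than that median, from 17.4 CPM. Part of the counts of Foxp3 may belong to overlapping genes such as Gm36995. A difference due to CIA itself and an exchange of the labels of whole groups stay open and untested, and Th17, follicular and T cell receptor genes that rose in CIA may reflect the same difference in CD4 cells.

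Interferon response genes were lower in CIA and higher after luteolin, with medians of -1.56 and 2.36. The share of B cells is argued against for the rise after luteolin, where the interferon median lay 3.006 above that of the B cell list (2 SE 0.536). In that comparison 1 of 18 B cell genes rose and 4 fell. The share of B cells stays open for the fall in CIA, where the B cell median was -1.23 beside -1.56. Scaling of the libraries is argued against in luteolin against CIA, as the interferon median lay 2.40 above that of all tested genes (2 SE 0.35), a difference that scaling does not move. Each SE is over genes, which move together, so it does not measure the spread between libraries. The share of monocytes and macrophages stays open: the medians of both lists had the same sign in 3 of 3 comparisons, but the macrophage median was the smaller in size in CIA against control (-0.84) and the larger in luteolin against CIA (3.20) and against control (1.44 against 0.79). Macrophages, which a selection for CD4 would mostly remove, could carry part of the change; their list shares no gene with the interferon list, and its most abundant members Lyz2, Mpeg1 and Ctss were at 1890.4, 1018 and 207 CPM in CIA and 2159.6, 1009.6 and 1898 with luteolin. An effect of CIA or of luteolin on interferon signalling itself stays open and was not tested separately.

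B cell genes were lower in CIA than in control and uneven among the CIA libraries, with Cd79a at 81.2, 53.3 and 24.1 CPM in CIA replicates 1 to 3. A lower share of B cells as the cause of the other marker changes is argued against, since the neutrophil median lay 2.787 above the macrophage median in CIA against control (2 SE 1.18), where a dilution alone would raise both alike. That SE is over the genes of a list, which move together, so it does not measure the spread between libraries. Tested gene by gene, 16 of 19 neutrophil genes rose and none fell, while 10 of 19 macrophage genes fell and 5 rose. CIA replicate 3 alone is argued against too, because without it the list was still called lower (camera adjusted p = 8.68e-06; 1.42e-07 to 0.509 over the alternatives tested with camera), with 14 of 18 genes lower, 1 higher and a median of -0.87. Whether the preparations or the animals differed in B cells stays open, and a difference due to CIA was not tested apart from this.

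With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 9886, 9148 and 8708 genes in CIA against control, luteolin against CIA and luteolin against control, where the highest of the other splits gave 0 in each, so 1 of 10 splits gave as many. It gave 26, 16 and 24 lists, where the highest of the others gave 20, 21 and 19, and 1, 3 and 1 of the 10 splits gave as many. The Th17 list had an adjusted p of 1.03e-06 in CIA against control, where the lowest of the others was 0.000414 (1 of 10 splits as small). It had 0.467 in luteolin against CIA, where the lowest was 0.0121 (8 of 10 as small). Splits that called no gene still called 5 to 21 lists at the preset correlation. Each of these other splits had libraries of both groups on both sides, so it kept part of the group difference and added the rest to the spread. Neither its 0 genes nor its lists therefore measure false calls. With an estimated correlation 2, 2 and 5 lists were called, so a list called at the preset correlation alone is weakly supported. Il21 had 6776 counts over all libraries and the antisense gene Gm12534 within it 6531. The mitochondrial genes mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 had 3, 11, 7 and 3 counts over all libraries, while mt-Co1 had 654321 and the nuclear copy Gm10925 had 876580.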
